A study of Mus musculus with 6 samples.

How the data were processed

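RNA of mouse optic nerve was profiled by ribosomal-RNA-depleted, stranded total RNA sequencing in 6 libraries. The labels place 3 libraries in a group named mCherry, after a red fluorescent protein, and 3 in a group named hND6, after a mutant human ND6 gene. Per the labels' protocols, the mutant gene was carried into the eye by an injected lentivirus. The same treatment text stands beside both groups, and only the treatment label tells them apart. RNA was extracted with a Qiagen RNeasy kit, and libraries were made with a TruSeq Stranded Total RNA kit. The labels do not say whether the 3 libraries of a group came from separate animals. Xist and Y-linked genes place libraries of both sexes in each group, so no group came from a single animal. Whether each library was a separate animal stays unknown, so p-values measure the spread between these libraries, which may be partly technical.

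The deposited values are FPKM, fragment counts scaled by exon length and library size, per the labels. They cover 52636 genes, with symbol, position and exon length for each. The submitters' processing notes name CASAVA 1.4, Trim Galore, STAR and HTSeq, and the genome builds mm10 and GRCm38, without assigning a role to each. Positions are given on that mouse build as the gene table lists them. The 6 tables of single libraries held the same values as the combined table.

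The depth was read from the values. FPKM times exon length was a whole multiple of one step per library for at least 99.99% of the values above 0 (within 0.1 read), so whole reads could be recovered. Reads assigned to genes came to about 30500500, 34758900 and 25718400 in mCherry replicates 1 to 3 and to 34057700, 20253600 and 22045300 in hND6 replicates 1 to 3. The reads also bear on how genes were counted. Of 5245 genes lying inside a longer gene on the same strand, 19 (0.362%) had any read, against 2420 of 5118 genes (47.3%) nested on the opposite strand only. Counting over whole gene spans, with reads of overlapping genes dropped, would give this pattern, but the counting mode is not given in the sources used here. Igkc, the kappa constant gene, lies within another gene on its strand and is listed at 0 in all 6 libraries. Of the 13 mitochondrial protein genes 6 are listed near 0, and 5 of these have a near-identical nuclear copy, so an FPKM near 0 is not read as absence of the transcript.

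Tests were run in R 4.3.3 with limma 3.58.1. The 16157 genes with a mean of at least 0.5 FPKM over the 6 libraries were tested on log2(FPKM + 0.5) with limma (moderated test with an intensity trend), hND6 against mCherry, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates changes of genes at low values. The main test, the other settings listed as fixed beforehand, the gene lists and the rule for named genes were fixed before the data were examined. There were 48 lists of respiratory chain, stress, metabolic, cell type, response and technical genes, each with at least 5 tested members. They were tested with limma's camera at a preset correlation of 0.01 between genes. They were tested again with an estimated correlation and with limma's fry, which tests whether a list's genes move one way without comparing them with other genes. Members were also adjusted over the list alone. The share of summed FPKM from the 13 mitochondrial protein genes was compared with an exact two-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. Read ratios carry exact binomial 95% intervals, and a group without reads is given a floor of 3 reads over the group; both cover counting error only.

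Genes named in the text follow a rule: the 10 genes with the largest rises and the 10 with the largest falls among those past the threshold whose groups do not overlap. Where fewer passed, they were filled up with the genes of smallest p whose groups do not overlap. The rule adds the 3 members of smallest p of each list past the threshold, of the 4 respiratory chain lists and of the mitochondrial integrated stress response list, mt-Nd6, and the 2 most abundant members of the lists that mark other tissues. Predicted genes, pseudogenes and unnamed transcripts were left out. Some genes that the rule takes are not reported here. Genes outside this rule are said to have been chosen after their values were seen.

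Alternatives fixed beforehand were other pseudocounts (0.1 and 1), no filter and a filter of 1 FPKM, scaling to a constant sum (TPM scale), median-of-ratios scaling, quantile normalisation, a test without trend, and a robust test. Further ones were library weights, the replicate number as a block, limma's voom on the recovered reads, and leaving out each library. Chosen after the data were seen were sex as a covariate (read from Xist and Y-linked genes), leaving out mCherry 3 with hND6 1 or with hND6 2, and removing each library's trend with gene span. Overlaps of genes were found with GenomicRanges 1.54.1, copies of mitochondrial genes with blastn 2.17.0 against GENCODE transcripts of GRCm38, and plots were drawn with matplotlib 3.10.9. The tests were tested on simulated reads drawn for the 16157 genes of this comparison: of 50 genes of at least 2 FPKM changed in each size, 18% were recovered at 1.5-fold, 60% at 2-fold, 92% at 4-fold and 100% at 16-fold, and 10 unchanged genes were called. In the same simulation a list of 40 raised genes passed limma's camera at 0.05 and a list of 40 unchanged genes did not. Genes were simulated independently of each other, whereas estimated correlations in the data were 0.754 for ribosomal proteins and 0.956 for photoreceptors. The simulation therefore does not show how camera treats lists of correlated genes.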

Results

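Total RNA of mouse optic nerve was sequenced in 3 mCherry and 3 hND6 libraries. One group is named hND6, after a mutant human ND6, a gene for a subunit of respiratory complex I that is normally encoded in mitochondrial DNA. The other is named mCherry, after a fluorescent protein. The labels do not say what the mCherry group received, since the same treatment text stands beside both groups. Reads assigned to genes ran from about 20253600 in hND6 2 to 34758900 in mCherry 2. The comparison asks how the transcriptome of the optic nerve differs between the groups so named.

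Several transcripts of antibody-producing cells stood far higher in all 3 hND6 libraries than in all 3 mCherry libraries. Of 16157 tested genes 7 passed the adjusted p threshold of 0.05 in limma, all of them higher in hND6. All 7 encode immunoglobulin chains or the J chain that joins secreted IgA and IgM. The kappa variable gene Igkv6-32 (chromosome 6 of the mouse build, 70074024 to 70074603) stood at 215 ± 90.1 FPKM in hND6 and 0.238 ± 0.342 FPKM in mCherry (SD, n = 3 each), a log2 fold change of 8.20 ± 0.40 (SE; limma adjusted p = 0.00746). The IgG2c constant gene Ighg2c (chromosome 12, 113285325 to 113288932) stood at 113 ± 86.9 against 0.198 ± 0.252 FPKM, 7.15 ± 0.52 on the log2 scale (adjusted p = 0.0226). Jchain (chromosome 5, 88520512 to 88527891) stood at 25.4 ± 13.7 against 0.253 ± 0.183 FPKM, with a log2 fold change of 5.01 ± 0.38 (adjusted p = 0.0226).

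Igha, the IgA constant gene, rose from 0.335 ± 0.242 to 16.6 ± 4.48 FPKM (log2 fold change 4.36, limma adjusted p = 0.0169). The lambda variable gene Iglv1 rose from 0.138 ± 0.177 to 6.89 ± 1.83 FPKM (3.54, adjusted p = 0.0226). Ighg2b, the IgG2b constant gene, had 3097 reads in hND6 and 3 in mCherry, a ratio of 1222 per library size with a 95% counting interval of 418 to 5928 (limma adjusted p = 0.0424). The heavy variable gene Ighv1-42 had 355 reads in hND6 and none in mCherry, at least 140-fold higher against a floor of 3 reads over the group (adjusted p = 0.0166). A further 3 genes with non-overlapping groups did not pass: Iglc2 (100 reads against 0, at least 39.5-fold higher, adjusted p = 0.0586), G0s2, an inhibitor of triglyceride lipase (4.91 ± 0.424 against 1.93 ± 0.0496 FPKM, adjusted p = 0.0986), and Ighv1-9 (820 reads against 3, ratio 324 with an interval of 110 to 1572, adjusted p = 0.14). All immunoglobulin genes together had 13340, 6631 and 17467 reads in hND6 replicates 1 to 3, against 1024, 432 and 318 in mCherry (exact two-sided permutation p = 0.1, the smallest possible). In hND6 replicates 1 to 3, 37, 22 and 39 variable genes had at least 10 reads, of which 17, 8 and 19 reached 10 reads in that library alone.

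**Figure D1:**
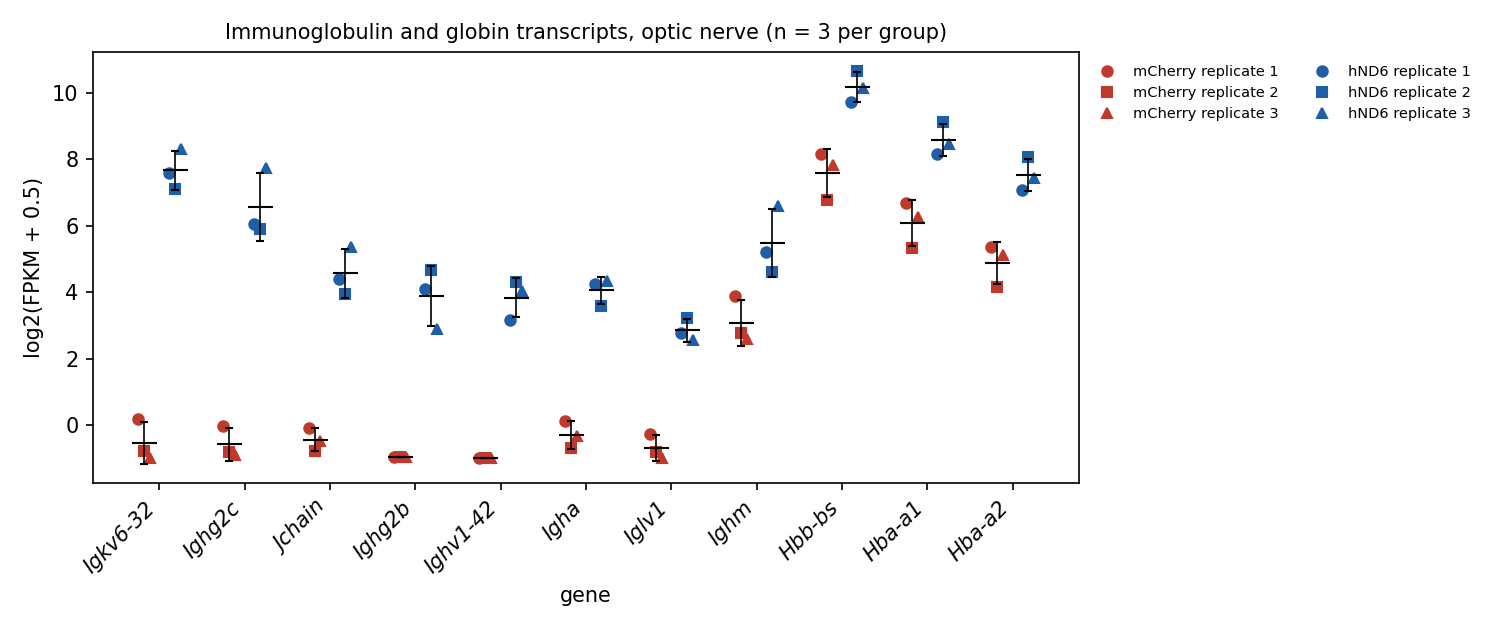
FPKM of 8 immunoglobulin and J chain genes and 3 globin genes in each library, on the log2(FPKM + 0.5) scale; points are libraries, bars are the mean and SD of 3 libraries per group. Every hND6 library lies above every mCherry library for each gene shown.

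The B and plasma cell list passed as a whole: all 10 tested members lay higher in hND6 (median log2 fold change 2.38), 4 of them past the threshold over all genes and 7 when adjusted over the list alone (camera adjusted p = 2.6e-11; adjusted p = 0.346 with an estimated correlation; fry adjusted p = 0.00567). Of the 18 genes of this list 10 were tested. Igha, Ighg2c, Jchain, Ighg2b and Iglc2 averaged under 0.5 FPKM in mCherry and passed the filter only through their hND6 values. The count of members higher and the median therefore depend on the filter. With no filter on low values the list median was 0.76, and the list still passed camera. Ighm, the IgM constant gene, was the list's second most abundant member at 52.3 ± 38.8 against 8.71 ± 4.80 FPKM (limma adjusted p = 0.187). Red blood cell transcripts differed in the same direction. Of the erythroid list 7 of 8 members lay higher and passed when adjusted over the list alone, none over all genes (median 2.29, camera adjusted p = 1.5e-07; adjusted p = 0.517 with an estimated correlation). Beta globin Hbb-bs stood at 1196 ± 384 against 207 ± 90.9 FPKM, and the alpha globin Hba-a1 at 396 ± 139 against 72.7 ± 31.3 FPKM. Hba-a2, the other alpha globin, had a log2 fold change of 2.65 ± 0.37 (limma adjusted p = 0.143 for each of the 3). The lists of T and NK cells (adjusted p = 0.529) and of neutrophils and mast cells (adjusted p = 0.765) did not pass camera. The count of 7 genes varied when single libraries were left out: 0 genes passed without mCherry 2 (1948 at an unadjusted p under 0.05), 1 without mCherry 1 or hND6 1, 2 without hND6 2, 5 without hND6 3 and 116 without mCherry 3. The log2 fold change itself moved little in these settings, from 7.89 to 8.56 for Igkv6-32 and from 6.56 to 7.48 for Ighg2c. With voom on recovered reads 0 passed (2352 unadjusted).

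No gene passed as lower in hND6 in limma (0 of 16157, smallest adjusted p = 0.103), although 978 were lower at an unadjusted p under 0.05. Limma's voom on recovered reads also called 0. Groups did not overlap for 3690 genes (22.8%), 2036 of them higher. Chance gives 10% on average over splits of the libraries, but genes vary together, so a single split can lie far from it. Other splits were not counted in this way, so the difference from 10% is not a measured excess. Genes of smallest p that lay lower with non-overlapping groups included Mir758, Immp2l, Inpp4b, Slc7a6, Gt(ROSA)26Sor, Zfp970, Mirlet7a-1, Fam49b and Gtdc1, and none passed. The microRNA gene Mir758 had 19 reads in mCherry and 0 in hND6, at least 5.35-fold lower (adjusted p = 0.143). Immp2l, a mitochondrial inner membrane peptidase subunit, stood at 61.7 ± 1.70 FPKM in hND6 and 85.0 ± 2.17 in mCherry (log2 fold change -0.46 ± 0.07, adjusted p = 0.143). The phosphatase gene Inpp4b had a log2 fold change of -0.47 ± 0.08 (adjusted p = 0.15). Immp2l spans 931499 bp. With each library's trend with gene span removed, chosen after the data were seen, its log2 fold change was -0.02 and that of Inpp4b -0.15.

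Transcripts of the endogenous respiratory chain lay mostly higher in hND6, by small amounts. The mouse counterpart of the delivered gene, mt-Nd6 (mitochondrial genome, 13552 to 14070), stood at 252 ± 18.9 FPKM in hND6 and 177 ± 73.7 in mCherry (log2 fold change 0.59 ± 0.27, limma adjusted p = 0.367). Single mCherry values were 141, 128 and 261 FPKM and hND6 values 260, 266 and 231 FPKM. The 8 tested mitochondrially encoded genes all lay higher (median 0.45), mt-Nd2 and mt-Cytb by 0.49 each, and none passed alone (camera adjusted p = 0.0246; adjusted p = 0.873 with an estimated correlation). That list did not pass without mCherry 1, mCherry 2, hND6 1 or hND6 2, nor with quantile normalisation, no filter or the gene span trend removed. The list median ran from 0.23 without mCherry 2 to 0.68 without mCherry 3. It was 0.04 with quantile normalisation and 0.16 with the gene span trend removed. The main median of 0.45 lay within the middle 95% of medians of 10000 random lists drawn for expression and length (0.34 to 0.63). The drawn genes were less expressed (mean log2 expression 7.19 against 8.51) and longer (mean log2 span 11.3 against 9.92), so this comparison decides little. The 13 mitochondrial protein genes made up 2.20 ± 0.293% of summed FPKM in hND6 and 1.94 ± 0.524% in mCherry, a difference smaller than the spread between libraries (exact two-sided permutation p = 0.7, smallest possible 0.1). Of these 13 genes 6 (mt-Atp6, mt-Atp8, mt-Co2, mt-Co3, mt-Nd3 and mt-Nd4l) averaged under 1 FPKM, so the share describes the other 7. Among those, mt-Nd4 had a nuclear transcript of 100% identity over 63.6% of its length, and mt-Co1 one of 99.8% over 31.3%. Loss of reads in them is therefore not excluded. A large part of summed FPKM came from the predicted gene Gm23935, at 62252 of 365375 in mCherry 1 and 108218 of 450685 in hND6 3.

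Of the 35 nuclear complex I subunits 33 lay higher (median 0.25) and of the 34 nuclear subunits of complexes III, IV and V all 34 did (median 0.35), none past the threshold over all genes or over the list alone. On the TPM scale, where the median of all genes lay at -0.15, 27 of 35 (median 0.11) and 31 of 34 (median 0.21) lay higher, and both lists still passed. Camera gave adjusted p = 2.3e-07 and 9.6e-10, and adjusted p = 0.873 for both with an estimated correlation. Both medians lay within the middle 95% of medians of matched lists, which ran from 0.11 to 0.30 for complex I and from 0.28 to 0.46 for complexes III to V. Ndufs7 stood at 44.8 ± 2.62 against 32.7 ± 3.04 FPKM, Ndufb7 at 40.1 ± 1.14 against 29.3 ± 3.44, and Ndufb11 at 43.2 ± 2.79 against 29.0 ± 5.28. Uqcrc2 of complex III stood at 41.7 ± 0.543 against 34.5 ± 2.47 FPKM, Atp5e of complex V at 68.4 ± 8.31 against 43.1 ± 13.2, and Cox6a1 of complex IV had a log2 fold change of 0.49 ± 0.16. The 15 complex I assembly factors did not pass as a list (median 0.02, mean -0.01, 8 higher and 7 lower, camera adjusted p = 0.502). Yet 5 of them lay lower with non-overlapping groups and none higher. Fry without direction gave adjusted p = 0.00968, but 11 of the 48 lists fell under 0.05 in that test. On the TPM scale 2 assembly factors lay higher and 13 lower, with a median of -0.12 beside -0.15 for all genes. Of smallest p were Ndufaf5 (-0.44), Ndufaf2 (-0.35) and Ndufaf6 (-0.33), and none passed the threshold.

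Library mCherry 3 stood apart from the other mCherry libraries on the first principal component (46.9% of the variance); several calls differed without it. It held transcripts of neurons, chosen after their values were seen. Tbr1, a gene of forebrain neurons, stood at 7.18 FPKM in mCherry 3, 1.94 in hND6 1 and at most 0.459 in the other libraries. Thy1, a more general neuronal gene, stood at 69.3, 22.8 and at most 14.1 FPKM. A forebrain origin thus rests on Tbr1 alone. Sex, read from Xist and Y-linked genes, also varied: mCherry 1 and 3 and hND6 3 were female. Without mCherry 3, 116 genes passed as higher and 15 as lower, all of them close to the threshold (smallest limma adjusted p = 0.0448). With hND6 1 left out as well, chosen after the data were seen, 1 gene passed as higher and 0 as lower (3289 at an unadjusted p under 0.05). The 116 included 26 ribosomal protein genes, mt-Nd6 (log2 fold change 0.91, adjusted p = 0.0448, over all alternatives 0.0448 to 0.85), 8 members of the nuclear complex I list, among them Ndufb11, and 12 of the list of complexes III to V, among them Cox6a1 and Atp5e. Their median gene span was 2573 bp, that of the 15 lower genes 83003 bp, and that of tested protein-coding genes 24002 bp.

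**Figure D2:**
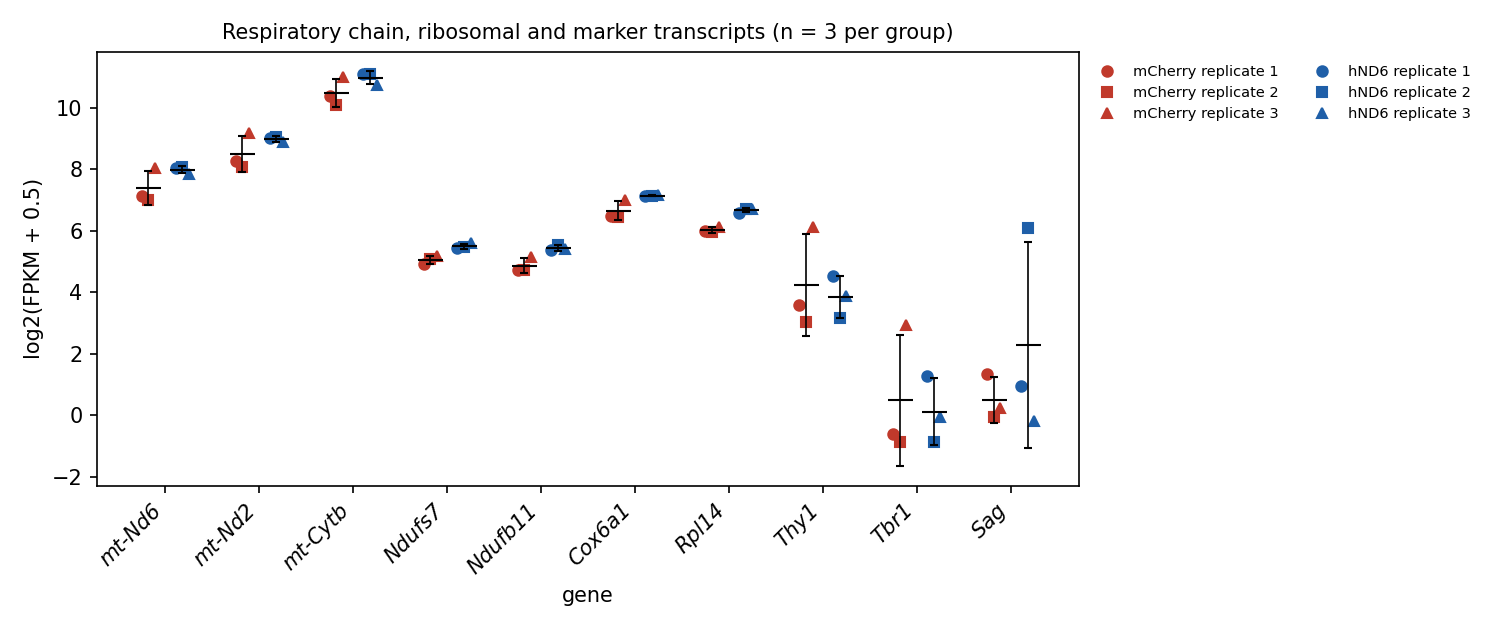
FPKM of respiratory chain, ribosomal and cell marker genes in each library on the log2(FPKM + 0.5) scale; points are libraries, bars are the mean and SD of 3 libraries per group. Thy1 and Tbr1 are highest in mCherry replicate 3, and Sag in hND6 replicate 2.

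Ribosomal protein genes, which encode the protein part of the ribosome, formed the most uniform group. All 57 tested members lay higher in hND6 with non-overlapping groups (median log2 fold change 0.59), none passed over all genes and all 57 passed when adjusted over the list alone (camera adjusted p = 6.2e-44; adjusted p = 0.517 with an estimated correlation; fry adjusted p = 0.0455). Rpl14 had a log2 fold change of 0.65 ± 0.08, and Rpl5 stood at 52.2 ± 1.91 against 36.2 ± 1.15 and Rpl9 at 46.3 ± 0.636 against 32.3 ± 1.80 (limma adjusted p = 0.143 each). Fold changes followed the length of genes on the chromosome. Over 13678 protein-coding genes the Spearman correlation between log2 fold change and gene span was -0.54, across genes, which are not independent replicates. The median log2 fold change was 0.34 for 761 genes spanning under 3 kb and -0.37 for 450 genes spanning over 300 kb. Genes over 300 kb did not separate the groups: their median deviation was 0.07 in hND6 1, 0.02 in mCherry 1 and 0.35 in mCherry 3. Among 10000 random lists matched to the ribosomal list on mean expression, gene span and exon length, the middle 95% of medians ran from 0.38 to 0.49. With each library's trend with gene span removed, chosen after the data were seen, the median of the ribosomal list was 0.39 and the list still passed.

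**Figure D3:**
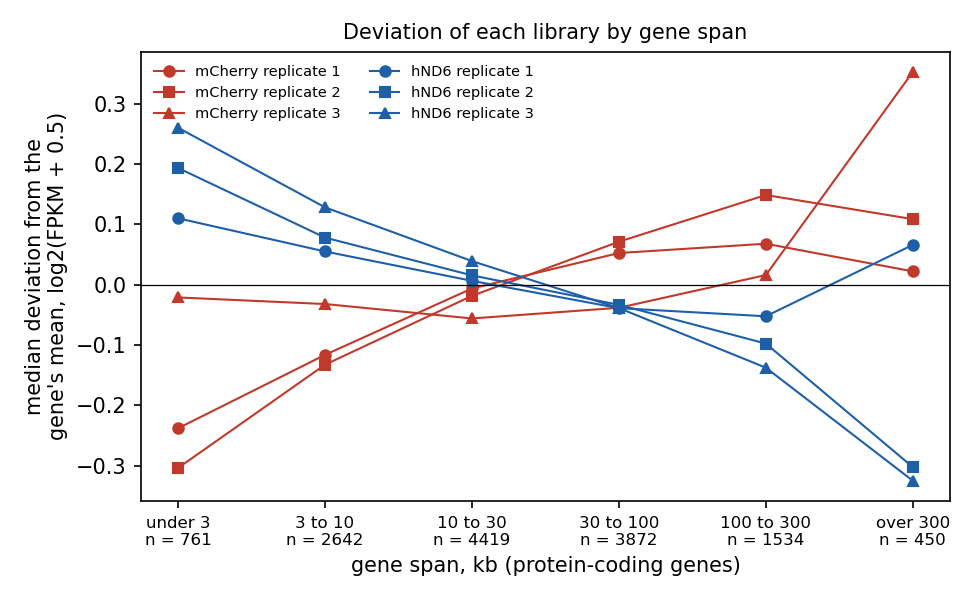
Median deviation of each library from the gene's mean over 6 libraries, in log2(FPKM + 0.5), for protein-coding genes in 6 classes of gene span; lines are libraries and n is the number of genes. Genes under 3 kb lie above 0 in all 3 hND6 libraries and below 0 in all 3 mCherry libraries. Genes over 300 kb are highest in mCherry 3, and hND6 1 lies above mCherry 1.

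Across all 48 lists, 21 passed camera at the preset correlation, all 21 higher in hND6, and 0 passed with an estimated correlation (smallest adjusted p = 0.346). Splits of the 6 libraries other than the real one passed 10 to 24 lists, so passing at the preset correlation alone says little about the groups. Directional fry called 3 of the 48, B and plasma cells, ribosomal proteins and structural noncoding RNAs. Of the 21, 11 had a median above the middle 95% of medians of lists matched on expression and length. The other 10 lay within it, though the lists drawn for mitochondrially encoded and structural noncoding genes matched poorly: the 3 respiratory chain lists, the mitochondrial integrated stress response, glycolysis, cholesterol synthesis, myelin, astrocytes, antigen presentation and structural noncoding RNAs. Of the glial lists that passed camera, microglia and Schwann cells lay above it. Matched lists were drawn at random and need not share the correlation estimated within lists (0.956 for photoreceptors, 0.819 for interferon-stimulated genes). Their middle 95% may thus be too narrow, and lying above it does not show an effect of the group. The interferon list lay above it, yet its median was -0.03 without mCherry 2. Of 22 microglia genes 19 lay higher (median 0.44, camera adjusted p = 3.2e-05; adjusted p = 0.873 with an estimated correlation). The list median ran from 0.27 without mCherry 2 to 0.64 without mCherry 1. None passed over all genes and 4 passed when adjusted over the list alone, among them P2ry12, a purinergic receptor of resting microglia (22.0 ± 0.822 against 14.9 ± 0.834 FPKM), Siglech (17.4 ± 0.417 against 12.9 ± 1.23) and Tmem119 (25.6 ± 4.92 against 17.0 ± 0.383). Activated microglia and macrophage genes did not pass (camera adjusted p = 0.385).

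Of 27 myelin and oligodendrocyte genes 25 lay higher (median 0.28, camera adjusted p = 0.000133; adjusted p = 0.873 with an estimated correlation), with Cnp at 696 ± 66.6 against 476 ± 92.9 FPKM, Car2 at 388 ± 28.1 against 283 ± 40.8 and Ermn at 172 ± 12.4 against 122 ± 24.5. The myelin list did not pass without mCherry 3, with mCherry 3 and hND6 2 left out (chosen after the data were seen) or with quantile normalisation. Its median ran from 0.17 without mCherry 3 to 0.43 without mCherry 2. With quantile normalisation it was 0.08, and on the TPM scale 0.13 with 20 of 27 higher. Medians of lists matched to the myelin list ran from 0.17 to 0.34. Astrocyte genes (median 0.21, 18 of 22 higher, camera adjusted p = 0.000577; adjusted p = 0.699 with an estimated correlation) included S100b (403 ± 28.8 against 260 ± 47.3 FPKM), Sox9 and Ppp1r3c. The astrocyte list did not pass with quantile normalisation (median 0.07). On the TPM scale its median was also 0.07, with 16 of 22 higher. Medians of lists matched to the astrocyte list ran from 0.05 to 0.27. Schwann cell genes Pou3f1, Fgl2 and Pllp (list median 0.35, camera adjusted p = 0.0171, not past the threshold without mCherry 2, mCherry 3, or mCherry 3 and hND6 2) and the fibroblast and meningeal genes Mgp, Igfbp2 and Foxc1 (median 0.29, camera adjusted p = 0.000577) had adjusted p = 0.699 and adjusted p = 0.873 for their lists with an estimated correlation. Mgp, an inhibitor of calcification, stood at 165 ± 23.3 against 98.2 ± 6.26 FPKM. The median of the fibroblast and meningeal list ran from 0.18 without mCherry 1 to 0.37 without hND6 3, and was 0.14 on the TPM scale.

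Of 27 antioxidant and NRF2 target genes 25 lay higher (median 0.33) and 6 passed when adjusted over the list alone, none over all genes (camera adjusted p = 1.6e-07; adjusted p = 0.517 with an estimated correlation). Gstp1, a glutathione transferase, stood at 112 ± 16.3 against 65.0 ± 5.08 FPKM, Gpx4 at 125 ± 7.97 against 90.9 ± 3.31 and Gpx1 at 143 ± 24.7 against 91.3 ± 5.91. The unfolded protein response list, with Xbp1, Canx and Dnajb9, had a median of 0.25 (camera adjusted p = 0.00109; adjusted p = 0.873 with an estimated correlation). Leaving out single libraries, that median ran from 0.12 to 0.34. On the TPM scale it was 0.11, with 12 of 18 members higher. The mitochondrial integrated stress response list, with Slc3a2, Atf5 and Nupr1, had a median of 0.13 (camera adjusted p = 0.0207; adjusted p = 0.699 with an estimated correlation). The glycolysis list, with Slc16a1, Aldoc and Ldhb, had a median of 0.19 (camera adjusted p = 0.0311; adjusted p = 0.873 with an estimated correlation). The glycolysis median ran from 0.04 without mCherry 2 to 0.30 without mCherry 3. On the TPM scale it was 0.05, with 12 of 22 members higher. The cholesterol synthesis list, with Sc5d, Hmgcs1 and Sqle, had a median of 0.14 (camera adjusted p = 0.0108; adjusted p = 0.873 with an estimated correlation). None of these 4 lists had a member past the threshold over all genes or when adjusted over the list alone. Single libraries ended these calls: mCherry 3 or hND6 3 for the unfolded protein and mitochondrial stress lists, mCherry 2 or hND6 3 for glycolysis and mCherry 1 for cholesterol synthesis. Both stress lists also did not pass with mCherry 3 and hND6 2 left out. The mitochondrial one did not pass either with the gene span trend removed, although its median was still 0.13 there. Glycolysis did not pass with quantile normalisation or the filter of 1 FPKM, nor cholesterol synthesis with sex in the model. On the TPM scale the medians of the mitochondrial stress and cholesterol lists lay just below 0. There the mitochondrial stress list did not pass and the cholesterol list did.

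Immediate early genes (Klf2, Ier3 and Ier2 of smallest p; median 0.44, camera adjusted p = 0.0054), antigen presentation genes (H2-DMa, Cd74 and Psmb10; median 0.24, adjusted p = 0.0246), interferon-stimulated genes (Ifi27, Bst2 and Ifi35; median 0.33, adjusted p = 0.0254) and structural noncoding RNAs (Rpph1, Rn7s1 and mt-Rnr2; median 0.53, adjusted p = 0.013) also passed at the preset correlation. With an estimated correlation their adjusted p = 0.873, 0.873, 0.926 and 0.517. Without mCherry 2 the first 3 of these lists did not pass and the interferon median was -0.03. The antigen presentation list also failed without hND6 3, and the interferon list without hND6 2, hND6 3, or mCherry 3 and hND6 2. With the gene span trend removed the immediate early, antigen presentation and structural noncoding RNA lists did not pass. Structural noncoding RNAs did not pass either with quantile normalisation, the filter of 1 FPKM, or mCherry 3 and hND6 1 left out. Rpph1, the RNA of ribonuclease P, stood at 1685 ± 105 against 815 ± 108 FPKM. Photoreceptor genes passed too (20 of 20 higher, median 1.13, camera adjusted p = 0.00213; adjusted p = 0.873 with an estimated correlation), and their level came mainly from one library. The list summed to 295 FPKM in hND6 2 and to at most 16.6 FPKM in each other library, with Sag at 68.3 FPKM in hND6 2, beside Rom1, Pde6a and Pde6g. Without hND6 2 the median of the photoreceptor list was 0.07 and the list did not pass.

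Neuronal lists did not pass with all libraries, and their direction varied with the library left out. The 22 neurofilament and axonal genes had a median of -0.29 (3 higher, 19 lower, camera adjusted p = 0.492), with Kif5a, an axonal motor, at 601 ± 175 against 616 ± 147 FPKM and Syt11 at 130 ± 12.2 against 110 ± 7.16. The 12 retinal ganglion cell genes had a median of -0.27 (adjusted p = 0.688), with Rbpms at 19.5 ± 4.33 against 26.3 ± 5.47 FPKM. Spp1 had no settled direction: it stood at 68.7, 6.43 and 8.10 FPKM in mCherry and at 21.6, 16.4 and 19.5 in hND6. Its log2 fold change was 0.29, and from -0.32 to 1.34 when single libraries were left out. The neurofilament and axonal list summed to 1641 FPKM in mCherry 3 and to 758 to 1171 in the other libraries. Without mCherry 3 its median was 0.35 and it passed as higher in hND6, and without mCherry 2 its median was -0.78 and it passed as lower. The ganglion cell list had a median of 0.31 without mCherry 3 and did not pass. The lists of the axon injury response (median 0.05, adjusted p = 0.429), apoptosis and p53 targets (-0.03, adjusted p = 0.904), reactive astrocytes (0.20, adjusted p = 0.114), complement (0.11, adjusted p = 0.931) and cytokines (0.11, adjusted p = 0.619) did not pass either.

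**Figure D4:**
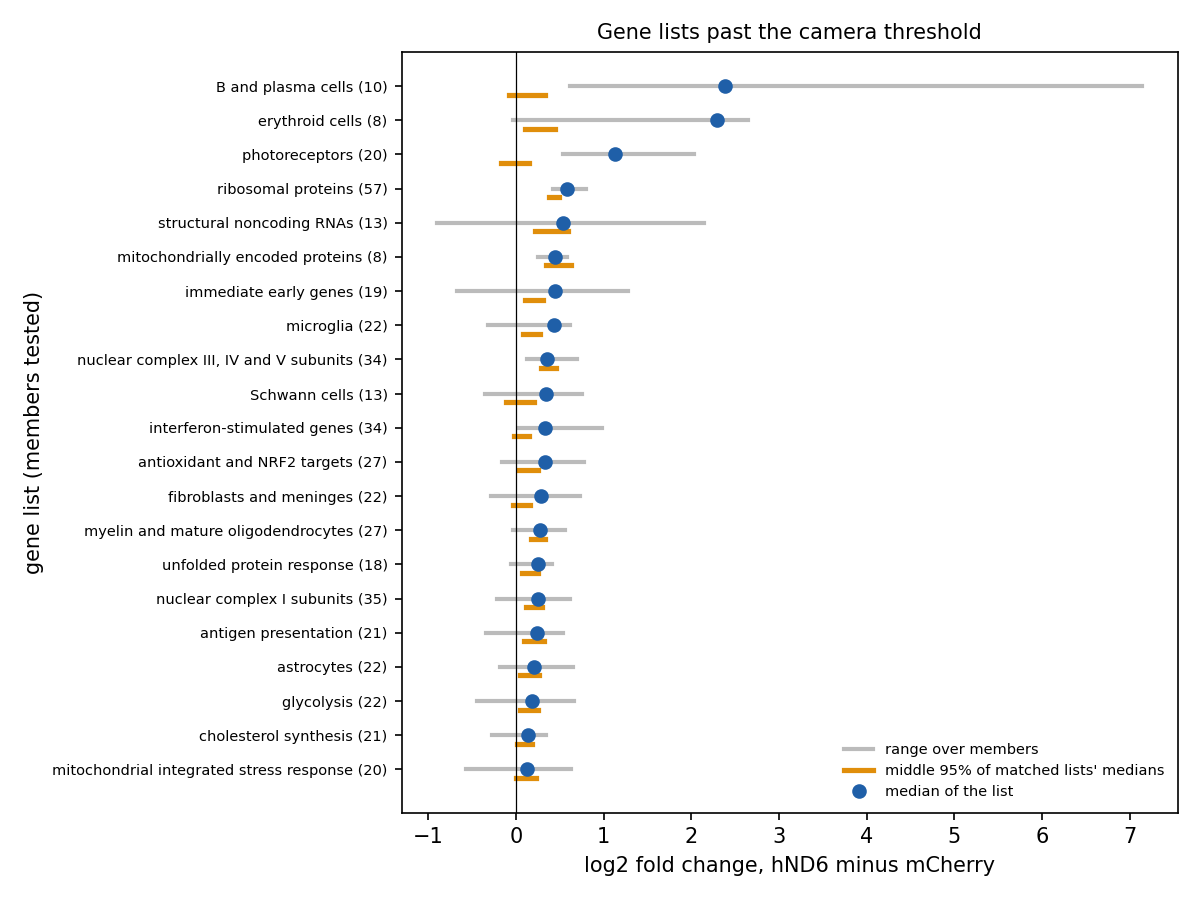
The 21 gene lists past the camera threshold at the preset correlation, with log2 fold change of hND6 minus mCherry on the horizontal axis: points are list medians, grey bars the range over members, and orange bars the middle 95% of medians of lists matched on expression and length. Medians run from 0.13 for the mitochondrial integrated stress response to 2.38 for B and plasma cells.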

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

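Sex as a covariate, the libraries left out in pairs and the removal of the gene span trend were chosen after the data were seen. Against 7 genes higher in hND6, a filter of 1 FPKM, median-of-ratios scaling and the robust test gave 7. The other pseudocounts, TPM scale, quantile normalisation, no trend, library weights and the span trend removed gave 5 to 8, all immunoglobulin or J chain genes except G0s2 with no trend. No filter on low values gave 1 gene over more genes tested, and voom on the recovered reads gave 0 (2352 at an unadjusted p under 0.05). Sex in the model gave 4, libraries mCherry 3 and hND6 1 left out gave 1, and libraries mCherry 3 and hND6 2 left out gave 0 (2437 unadjusted). The left-out settings have fewer libraries; otherwise the cause was not tested. Leaving out single libraries gave 0 to 116 genes higher and 0 to 15 genes lower, the lowest without mCherry 2 (1948 unadjusted) and the highest without mCherry 3. The replicate numbers did not pair the libraries: correlations of same-numbered deviations were -0.416, 0.363 and -0.197, and not every library correlated best with its own number. With the replicate block 0 genes passed as higher and 0 as lower (1789 unadjusted), 21 lists passed, and the mitochondrial share differed by 0.263 percentage points. That share differed by -0.010 to 0.512 points when single libraries were left out, the lowest without mCherry 2, and the cause was not tested. Between 16 and 22 lists passed camera over the 22 alternatives. The 8 lists that passed in each were ribosomal proteins, B and plasma cells, erythroid cells, both nuclear respiratory chain lists, antioxidant genes, microglia, and fibroblasts and meninges. Leaving out single libraries, their medians ran from 0.51 to 0.66, 2.25 to 3.04, 1.92 to 2.57, 0.20 to 0.37 (complex I), 0.25 to 0.52 (complexes III to V), 0.30 to 0.44, 0.27 to 0.64 and 0.18 to 0.37 in that order. The interferon-stimulated list had a median of -0.030 without mCherry 2 and up to 0.742 without another single library, and the cause was not tested. The neurofilament and axonal list, which did not pass with all libraries, passed as higher without mCherry 3 and with mCherry 3 and hND6 2 left out, and as lower without mCherry 2. Depth limits genes with few reads: at 0 reads in mCherry the folds given are lower bounds.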

Other observations

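The tests of gland tissue, blood, reads carried between hND6 libraries, the removed span trend, brain tissue, sex and the spacing of nuclear copies were chosen after the result was seen. The genes of this paragraph were likewise chosen after their values were seen. Cdk8 was listed at 653, 559 and 1925 FPKM in mCherry replicates 1 to 3 and at 2092, 2898 and 2884 FPKM in hND6, and passed limma without mCherry 3 but not with all libraries. Cdk8 spans 71587 bp with 2973 bp of exon. If whole spans were counted, its values may hold reads from introns, so they are not read as Cdk8 messenger RNA alone. The histone genes Hist1h4d, Hist1h1e and Hist1h4c also passed without mCherry 3, with log2 fold changes of 1.30, 1.08 and 1.01. Of the list of mitochondrial biogenesis and dynamics, which did not pass camera (14 higher and 14 lower, median -0.003, adjusted p = 0.828), Park2 stood at 87.6 FPKM in hND6 against 118 in mCherry, Pink1 at 112 against 84.9 and Fis1 at 112 against 87.6. These 3 passed limma when adjusted over the list alone and none passed over all genes. Their values with the trend with gene span removed are not given here, so a part of that trend in them is not excluded.

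Immunoglobulin transcripts were higher in hND6. Gland or eye surface tissue would bring its own transcripts, yet 0 of its 17 detected markers under 1 FPKM in mCherry lay higher in all 3 hND6 libraries, while 8.70% of all 23 detected markers did (Cdh1 and Perp). The sum over all markers was 39.8 ± 0.990 FPKM in hND6 against 31.1 ± 7.09 in mCherry, a difference beyond the SD, so markers of high baseline leave this undecided. Reads carried over from a single hND6 library would keep one ratio of Ighg2c to Ighg2b, but that ratio differed 12.8-fold between hND6 libraries. A larger amount of blood of the same composition would raise immunoglobulins and globins alike. Summed globins were 5.71-fold higher in hND6, yet depth-scaled immunoglobulin reads over globin FPKM were 0.0731, 0.0706 and 0.0343 in mCherry and 0.291, 0.127 and 0.448 in hND6. That is a 4.87-fold difference, which argues against such blood as the whole source. A part from blood, or blood cells of another composition, may contribute and stays open: summed S100a8 and S100a9 differed by 1.52 FPKM, within the spread. A presence of plasma cells in the nerve with hND6 is the biological hypothesis and was not tested. Only 1 of the 10 splits of the 6 libraries, the real one, gave as many as 7 genes. The highest other gave 5, but it set the female libraries against the male ones, so it is not an arbitrary grouping. Each remaining split gave 0 or 1 gene, and 10 splits are too few for a share under 0.05.

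Ribosomal protein genes were higher in hND6 and long genes lower in the group median, though over 300 kb hND6 1 lay above mCherry 1 and mCherry 3 stood highest. A different share of unspliced RNA is a candidate explanation if reads in introns were counted, yet the ribosomal median of 0.59 lay at the 100th percentile of lists matched on expression, gene span and exon length, whose middle value was 0.45. With each library's trend with gene span removed the median was 0.39 and the list still passed. Matching on gene span and exon length does not match the share of reads in introns. Random lists also need not share the correlation estimated within the ribosomal list (0.754), and matched genes were slightly longer and less expressed. These values therefore cannot decide whether such a difference accounts for part of the shift or for all of it. Without mCherry 3 and hND6 1, the libraries with the most Tbr1, the ribosomal median was 0.70 and that of genes over 300 kb -0.40. With sex in the model they were 0.64 and -0.38. These values argue against brain tissue in those libraries and against sex as the whole cause. A response to hND6 stays open and was not tested. For the 21 lists, 2 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. Splits other than the real one passed 10 to 24 lists, so the count of lists says little about the groups.

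Of the 13 mitochondrial protein genes 6 were listed under 5 FPKM beside 7 at over 100 FPKM. Reads shared with near-identical nuclear copies are a candidate explanation: 5 of the 6 had a nuclear transcript of at least 99% identity over at least 80% of their length, and 0 of the 7 did. For mt-Atp8 no annotated copy of that length was found, so annotated copies do not account for all 6. The search covered annotated transcripts only, so it cannot exclude an unannotated copy of mt-Atp8. The nuclear copies of its neighbours mt-Co2 and mt-Atp6 lay 233 bp apart on chromosome 1, against 230 bp in the mitochondrial genome, consistent with an unannotated copy of mt-Atp8 between them. No biological explanation was tested.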
